A study of Mus musculus with 24 samples.

How the data were processed

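Polyadenylated RNA of MIN6 cells, a mouse insulinoma line that secretes insulin, was sequenced after transfection of a plasmid for GFP, the control, or for EIF2A fused to GFP (EIF2A-GFP). Cells of each construct received 1 µM thapsigargin for 1 or 3 h or the vehicle DMSO, written here as 0 h. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER) and thereby causes ER stress. The design has 6 groups of 4 libraries, 24 in all, called here GFP or EIF2A at 0, 1 or 3 h. Groups and replicate numbers were taken from the sample titles, which number the replicates of each group from 1 to 4. Columns of the count table were matched to samples through the column names that the sample descriptions give. The column names number the same replicates from 2 to 5, so replicate 1 here is the column with suffix 2.

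The submitters' processing notes name bcl2fastq, STAR and the mouse build mm10. The program that counted reads, the annotation, the strand setting and tool versions are not given in the sources used here. The deposited values are raw counts per gene, whole numbers without normalization. The table holds 24421 genes and 2 further lines that name no gene, for reads outside any gene and reads that fit more than 1. These 2 lines were left out. Gene coordinates and exonic lengths came from GENCODE M21 on GRCm38, the same build as mm10, and 96.3% of the genes tested without replicate 1 had a length. A trend on exonic length was removed by a loess curve per library, as a check without replicate 1.

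Total counts per library, the depth, ran from 10.5 to 22.2 M (mega) counts. Libraries of the constructs differed in it, at 16.7 to 22.2 M counts for GFP and 10.5 to 22.1 M counts for EIF2A. At the lowest depth, a value of 1 in counts-per-million (CPM) is about 10.5 counts. Reads carry no molecular identifiers, so counting error is a lower limit of the error. The labels do not say whether the 4 replicates are separate cultures. The p-values therefore measure the spread between these libraries only, which may be technical. Pairs of libraries of a group were also compared by chi-square over degrees of freedom, which is 1 for counting error alone. It ran from 1.33 to 20.6 within replicates 2 to 4 and from 69.5 to 156.1 with replicate 1. Some libraries of replicates 2 to 4 thus differ by little more than counting error.

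Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default filter on low counts (minimum count 10, minimum total 15), robust dispersions, a quasi-likelihood fit of the 6 group means over all 24 libraries (18 residual degrees of freedom) and the quasi-likelihood F test. Each contrast was adjusted by Benjamini-Hochberg over its 13761 genes, and an adjusted p under 0.05 was called. Contrasts were 1 h against 0 h, 3 h against 0 h and 3 h against 1 h within each construct, EIF2A against GFP at each time and averaged over the 3 times, and the interaction at 1 h and at 3 h, which is the response of EIF2A minus that of GFP. Values are log2 fold changes ± standard error (SE) unless another measure is named. "Rose" and "fell" stand for an adjusted p under 0.05 throughout.

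The text names genes by a rule set before the data were examined. It takes the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM, a gene symbol and, for contrasts of 2 groups, no overlap between their libraries. It adds 4 members per list with the smallest p, or the 2 most abundant where none was called, and 11 genes in every contrast: Eif2a, Ins1, Ins2, Atf4, Ddit3, Atf3, Hspa5, Xbp1, Txnip, Mafa and Pdx1. A gene named in one contrast may be given its value in another.

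Of 32 gene lists fixed before the data were examined, 31 had measured members, as the table lists no mitochondrially encoded gene. They cover integrated stress response (ISR) targets of ATF4, tRNA synthetases, ER chaperones, ER-associated degradation (ERAD), ER translocation and transport, substrates of regulated IRE1-dependent decay (RIDD), immediate early genes, beta cell identity, secretory granules, genes disallowed in beta cells, apoptosis, p53 targets, ribosomal proteins, translation factors, nuclear genes of oxidative phosphorylation (OXPHOS), cholesterol synthesis, interferon response, NF-κB targets, NRF2 targets, heat shock, glycolysis and hypoxia, S phase, G2/M, autophagy and lysosome, and markers of alpha, delta/PP/epsilon, acinar, duct, mesenchymal, endothelial and macrophage cells. Members overlap between some lists, such as Xbp1 among ER chaperones and Ddit3 among ISR targets. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. Each list was also counted, over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives.

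A response score was the mean log2 CPM of genes that rose minus that of genes that fell with time in a fit blind to construct (absolute log2 fold change of at least 1). Its difference between constructs was tested by a two-sided exact permutation of construct labels within times. Labels were permuted at each time separately, so the test takes the constructs as exchangeable at 0 h too and the libraries as independent.

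Other choices, set before the data were examined, were RLE, upper-quartile and library-total scaling, no filter and a stricter one (5 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, each contrast from its own libraries alone, a 2-fold minimum, removal of the 10 most abundant genes, replicate number as a block across constructs, and each library left out in turn. Some alternatives were chosen after seeing the data. These were all 6 replicate 1 libraries left out, replicate number as a block within each construct, called paired here, and the same as a random effect in limma-voom. The labels do not call equal numbers pairs. Pairing was tested from the correlation across genes of residuals from the group means: libraries of equal number within a construct had r of 0.51 to 0.93 over 24 pairs of libraries. Without replicate 1 this was -0.03 to 0.31 over 18 pairs, so most of the shared variation lies in replicate 1. Biological coefficients of variation were 0.246 as planned, 0.0571 paired and 0.0633 without replicate 1.

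The pipeline was tested on simulated data of the same groups with 200 changed genes. Each simulated library was drawn independently, without other differences between constructs and without variation shared by libraries of equal number. The rates below therefore need not hold for the real libraries, where replicate 1 stands apart. The planned test recovered 67 to 78% of 2-fold and 88 to 96% of 4-fold changes between 2 groups, and 36 to 44% and 84 to 86% of interactions. False calls made up 0.529 to 8.33% of calls over the 3 fits simulated.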

Results

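Gene counts were measured in 24 libraries of MIN6 cells, 4 for each of 6 groups: cells given a GFP plasmid or an EIF2A-GFP plasmid, each with vehicle (0 h) or with 1 µM thapsigargin for 1 or 3 h. The design asks how the transcriptome of a beta cell line answers ER stress over time, and whether extra EIF2A changes that answer. EIF2A is a translation initiation factor that can bring the initiator tRNA to the ribosome. It is not eIF2α, the product of Eif2s1, whose phosphorylation starts the integrated stress response (ISR). Depth was 17.4 to 22.2 M (mega) counts for GFP at 0 h, 18.1 to 21.5 at 1 h and 16.7 to 19.7 at 3 h. For EIF2A it was 10.5 to 18.1 M counts at 0 h, 14.1 to 22.1 at 1 h and 15.9 to 16.9 at 3 h. Insulin and amylin mRNAs led all genes: Ins2 took 4.10% of counts, Iapp 1.65% and Ins1 1.12%. Of 24421 genes listed, 4637 had no count, and 13761 were tested.

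Eif2a, the gene on the plasmid, was examined first as a check of the labels. It lies on chromosome 3 at 58525821 to 58557501 (GRCm38, plus strand) and shares 72 bases with Serp1 on the minus strand (58519817 to 58525892). In replicates 2 to 4, Eif2a was higher in the libraries labelled EIF2A at each time. At 0 h it was 139.2 ± 4.56 CPM (SD, n = 3) against 78.5 ± 0.636 in GFP, at 1 h 189.4 ± 11.6 against 92.2 ± 2.06, and at 3 h 189.1 ± 22.8 against 97.5 ± 5.62. In replicate 1 the order was the opposite at all 3 times. Eif2a stood at 269.4, 361.2 and 358.1 CPM in the GFP libraries and at 80.3, 96.9 and 104.3 CPM in those labelled EIF2A. The log2 ratio of EIF2A over GFP was 0.83, 1.04 and 0.95 in replicates 2 to 4 and -1.75, -1.90 and -1.78 in replicate 1. Over all 4 replicates the constructs therefore did not differ in Eif2a. Its log2 fold change was -0.02 ± 0.51 at 0 h, 0.06 ± 0.51 at 1 h and 0.05 ± 0.51 at 3 h, with adjusted p = 0.983, 0.942 and 0.960. Leaving out replicate 1, a choice made after seeing the data, gave 0.83 ± 0.07 at 0 h with adjusted p = 8.37e-09. Serp1 did not follow Eif2a, at 319.8 ± 17.7 CPM in EIF2A and 460.9 ± 11.7 in GFP at 0 h in replicates 2 to 4. The species and the ends of the EIF2A sequence on the plasmid are not given in the sources used here, so counts of the mouse gene may miss part of the plasmid's mRNA.

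**Figure D1:**
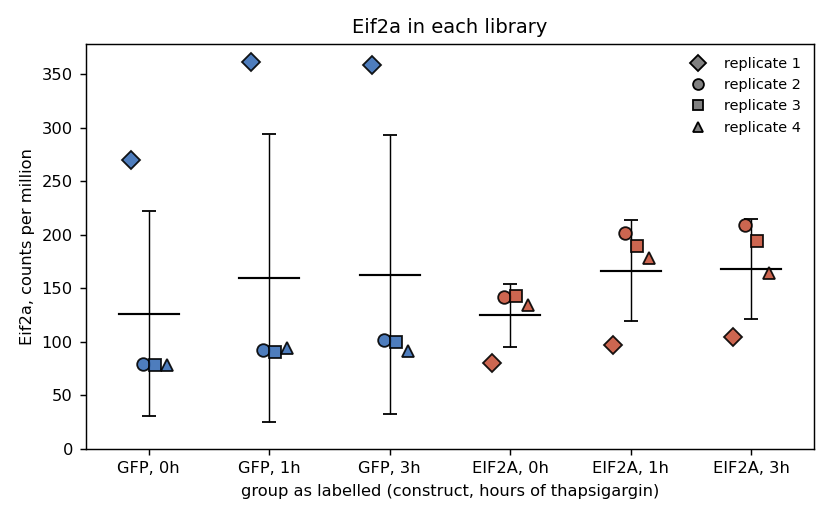
CPM of Eif2a in each of the 24 libraries, by construct and time, with 1 symbol per replicate number (replicate 1 as diamonds) and black lines for the mean ± SD of 4 libraries. Replicates 2 to 4 lie at 77.8 to 101.9 CPM in GFP and 134.0 to 208.9 CPM in EIF2A, while replicate 1 lies at 269.4 to 361.2 CPM in GFP and 80.3 to 104.3 CPM in EIF2A.

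The whole transcriptome showed the same arrangement. On the first principal component, 56.4% of the variance, replicates 2 to 4 lay at 44.9 to 47.6 in GFP and -53.1 to -42.2 in EIF2A, and replicate 1 at -40.0 to -36.1 in GFP and 44.0 to 46.7 in EIF2A. Across 9966 genes, which are not independent replicates, the EIF2A minus GFP difference of replicate 1 correlated with that of replicates 2 to 4 at r = -0.738, -0.732 and -0.745 at 0, 1 and 3 h. All comparisons keep the groups as labelled. Those between constructs are given with and without replicate 1, and "EIF2A" below stands for libraries labelled so.

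**Figure D2:**
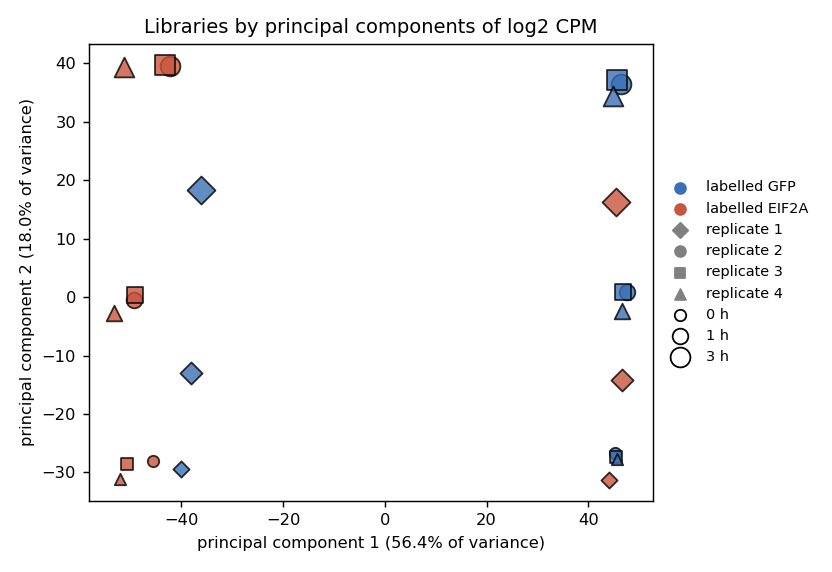
Principal components of log2 CPM over the 24 libraries, the first (56.4% of variance) against the second (17.96%), with construct as colour, replicate number as symbol (replicate 1 as diamonds) and time as symbol size. Replicate 1 libraries of GFP lie at -40.0 to -36.1 on the first axis, near the other EIF2A libraries, and those of EIF2A at 44.0 to 46.7, near the other GFP libraries.

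The first comparison sets 1 h of thapsigargin against vehicle in control cells. No vehicle group is labelled 1 h or 3 h, so here and below time and handling cannot be told apart from thapsigargin. In GFP cells, 796 genes rose and 329 fell, 50 and 1 of them by 2-fold or more (552 in all without GFP replicate 2 at 1 h). Among those that rose were transcription factors of the immediate early class, with Fosb at 1.88 ± 0.38, Egr4 at 1.57 ± 0.41 and Ier2 at 1.39 ± 0.17 (adjusted p = 0.00382, 0.0192 and 2.78e-05). Arc rose by 1.28, Klf10 by 1.16 and Junb by 0.91, and Gem, a small GTPase induced by calcium signals, by 1.41. Of 47 immediate early genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone), and the set moved up with a median of 0.79 (camera adjusted p = 1.86e-12; adjusted p = 0.122 with an estimated correlation).

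ISR genes were already higher at 1 h. Chac1, which degrades glutathione under ATF4, rose by 1.51 ± 0.21 (adjusted p = 1.19e-04), Atf3 by 1.36 ± 0.33 and Ddit3, which encodes CHOP, by 1.18 ± 0.27 (0.0130 and 0.00962). Atf4 mRNA itself rose by 0.59, Ppp1r15a, a phosphatase subunit for eIF2α, by 0.66 and Sesn2 by 0.58. Txnip, a glucose-induced inhibitor of thioredoxin, rose by 1.38 ± 0.35 (adjusted p = 0.0178). Of 38 ISR targets 10 rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 8.85e-06 and adjusted p = 0.291 with an estimated correlation. Among 20 tRNA synthetases 10 rose, Vars by 0.46 and Dars by 0.42 among them, and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 4.41e-09; adjusted p = 0.122 with an estimated correlation).

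Some genes of the ER's own machinery also rose at 1 h. Herpud1, a scaffold of ER-associated degradation, rose by 0.89, the chaperone Hsp90b1 by 0.69 and the disulfide isomerase Pdia4 by 0.63. Hspa5, the chaperone BiP, was at 0.43 ± 0.16 and Xbp1 at 0.36 ± 0.15 (adjusted p = 0.113 and 0.179). Paired by replicate number, they were at 0.45 and 0.34 with adjusted p = 5.06e-06 and 9.90e-06. Of 30 ER chaperones 4 rose and 0 fell (4 and 0 adjusted over the list alone, 15 and 2 paired), with camera adjusted p = 0.00125 and adjusted p = 0.581 with an estimated correlation. Of 24 ERAD genes 2 rose (camera adjusted p = 0.743). Of 35 translocation and transport genes 3 rose and 5 fell (camera adjusted p = 0.156).

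Several other sets shifted at 1 h. Replication-dependent histone genes were among the strongest single genes, with Hist1h1b at 2.46 ± 0.26, Hist1h1d at 2.01 ± 0.22 and Hist3h2a at 1.77 ± 0.21 (adjusted p = 5.76e-06, 9.66e-06 and 2.10e-05). These genes are near copies of each other, and polyA selection captures them in part only, so single members carry added uncertainty. Cell cycle genes rose in part, with the origin licensing factor Cdc6 at 0.57 and the spindle factor Dlgap5 at 0.76. In S phase 5 of 21 genes rose and in G2/M 8 of 23 rose and 1 fell (camera adjusted p = 9.13e-04 for both; adjusted p = 0.291 with an estimated correlation for both). In cholesterol synthesis, 3 of 25 genes rose, Fdft1 by 0.61 and Cyp51 by 0.56 among them (camera adjusted p = 9.13e-04; adjusted p = 0.546 with an estimated correlation). Of 63 OXPHOS genes 7 fell and 6 rose (13 and 6 adjusted over the list alone, 38 and 8 paired), with Sdha, a subunit of complex II, at 0.87 and Ndufa4, a subunit of complex IV, at -0.93 (median -0.18; camera adjusted p = 9.13e-04; adjusted p = 0.721 with an estimated correlation). Ribosomal protein genes had a median of -0.12 with 0 of 79 called by edgeR, and 40 lower and 2 higher paired (camera adjusted p = 9.13e-04, and 0.923 with an estimated correlation). Removing the length trend, without replicate 1, took the OXPHOS median from -0.19 to -0.10 and the ribosomal median from -0.14 to -0.06. With an estimated correlation, 6 set calls hold at 1 h without replicate 1, namely immediate early genes (adjusted p = 7.97e-05), ISR targets, ER chaperones and cholesterol synthesis (0.00178 each), S phase (0.00480) and tRNA synthetases (0.00617), and 0 hold paired (0.118 or more).

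Among beta cell genes at 1 h, the prohormone convertase Pcsk2 rose by 0.69 and Foxa2 by 0.64. Ins1, Ins2, Mafa and Pdx1 were at -0.19, -0.21, 0.19 and 0.14 with adjusted p of 0.672 or more, and paired values for Ins1, Ins2 and Pdx1 were -0.21, -0.22 and 0.14 (adjusted p = 0.0267, 0.0277 and 0.0472). Lowest were Ndufa4, the hypoxia-induced Ankrd37 (-0.89), the zinc finger gene Zfp704 (-0.84), S100a11 (-0.77) and Rragd, a Rag GTPase of the mTORC1 pathway (-0.75). Rassf10 rose by 1.74. Eif2a was at 0.34 ± 0.51 (adjusted p = 0.827) and paired at 0.28 (adjusted p = 5.94e-05). Paired, 3153 genes rose and 2979 fell at 1 h. These include all 1125 planned calls in the same direction.

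After 3 h, 2538 genes rose and 2005 fell in GFP cells, 483 and 144 by 2-fold or more. Among ISR genes, Atf3 rose by 3.32 ± 0.35, Chac1 by 2.97 ± 0.22, Ddit3 by 2.03 ± 0.28 and Sesn2 by 2.03 ± 0.10 (adjusted p = 3.78e-07, 5.82e-09, 9.44e-06 and 5.90e-11). Ddit3 went from 63.5 ± 14.7 to 259.0 ± 21.2 CPM (SD, n = 4). Ppp1r15a rose by 1.84, the folate enzyme Mthfd2 by 1.12 and Atf4 by 0.81. Of 38 ISR targets 30 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 1.30, camera adjusted p = 2.82e-19 and adjusted p = 0.0222 with an estimated correlation. Among tRNA synthetases 16 of 20 rose (17 adjusted over the list alone), Iars by 1.24 and Nars by 1.10, with camera adjusted p = 4.48e-10 and adjusted p = 0.0927 with an estimated correlation.

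ER genes split at 3 h. Herpud1 rose by 1.46, Xbp1 by 0.71 ± 0.15 (adjusted p = 0.00120) and Hsp90b1 by 0.53, while Edem1 fell by 0.79 and the ER cyclophilin Ppib by 0.63. Hspa5 was at 0.29 ± 0.16 (adjusted p = 0.183) and paired at 0.30 (adjusted p = 2.73e-04). Of 30 ER chaperones 3 rose and 5 fell (camera adjusted p = 0.878), and of 24 ERAD genes 5 rose and 4 fell (0.955). In both lists the median and mean, 0.01 and -0.01 for chaperones, differed in sign. The translocation and transport list went down. There 14 of 35 genes fell and 1 rose (14 and 1 adjusted over the list alone), with the channel subunits Sec61g and Sec61b at -0.82 and -0.81 and the oligosaccharyltransferase subunit Dad1 at -0.91 (camera adjusted p = 4.45e-04; adjusted p = 0.425 with an estimated correlation). Bloc1s1, a substrate of IRE1, fell by 1.22 ± 0.27 (adjusted p = 0.00148), 1 of 2 among 5 RIDD substrates that fell (camera adjusted p = 0.351).

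Of 47 immediate early genes 17 were higher at 3 h and 1 lower (17 and 1 adjusted over the list alone), among the higher Klf10 at 1.92 and Ier2 at 1.51 (camera adjusted p = 2.74e-05; adjusted p = 0.286 with an estimated correlation). NF-κB targets rose in 8 of 13 cases and fell in 1, with Relb at 1.92 ± 0.18 and Nfkb2 at 1.01 ± 0.14 (camera adjusted p = 0.0162; adjusted p = 0.0927 with an estimated correlation). Bbc3, which encodes the death factor PUMA, rose by 1.60. Over the apoptosis list 7 of 23 rose and 1 fell, with a median of -0.09, a mean of 0.29 and camera adjusted p = 0.320, upward. In S phase 12 of 21 rose and 0 fell (13 and 0 adjusted over the list alone), Cdc6 by 1.18 and Cdt1 by 0.97 (camera adjusted p = 8.76e-05; adjusted p = 0.124 with an estimated correlation). The histone genes Hist1h1b, Hist1h1d and Hist1h2ac rose by 4.30 ± 0.27, 3.99 ± 0.23 and 3.53 ± 0.43. Of 54 histone genes measured, a set chosen after its values were seen, 41 rose and 0 fell. Txnip rose by 2.37.

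Most OXPHOS genes and part of the glycolysis and hypoxia list fell at 3 h. Of 63 OXPHOS genes 44 fell and 3 rose (50 and 3 adjusted over the list alone), with Ndufa4 at -2.22 ± 0.18, Cox6b1 at -1.03 and Cox7b at -1.01 (median -0.50; camera adjusted p = 3.01e-14; adjusted p = 0.124 with an estimated correlation). The lactate transporter Slc16a3 fell by 2.31 ± 0.76 (adjusted p = 0.0230), Ankrd37 by 1.89, the glycolytic regulator Pfkfb3 by 1.59 and the glucose transporter Slc2a1 by 1.10. In the glycolysis and hypoxia list 5 of 20 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.00509; adjusted p = 0.701 with an estimated correlation). Ribosomal protein genes fell in 36 of 79 cases and rose in 0 (47 and 1 adjusted over the list alone), as with Rps28 at -0.65 and Rpl38 at -0.61 (median -0.39; camera adjusted p = 4.48e-10; adjusted p = 0.597 with an estimated correlation). NRF2 targets fell in 12 of 24 cases and rose in 1, with the glutathione transferase Gstm1 at -1.23 (camera adjusted p = 0.00229; adjusted p = 0.0934 with an estimated correlation). S100a11 was at -2.10 and Tnfsf9, a ligand of the TNF family, at -1.76.

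Some beta cell genes fell at 3 h. Ins2 fell by 0.98 ± 0.20 (adjusted p = 7.97e-04), from 45623 ± 10189 to 23121 ± 7326 CPM (SD, n = 4). Ins1 was at -0.99 ± 0.45 (adjusted p = 0.0995), and paired at -1.03 (adjusted p = 5.83e-12). The paralogs Ins1 and Ins2 share much of their sequence, so reads may pass between them. G6pc2, the islet glucose-6-phosphatase, fell by 1.34, the fatty acid receptor Ffar1 by 0.71, Iapp by 0.61 and the vesicle GTPase Rab3a by 0.51. Of 28 identity genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), and of 24 granule genes 4 fell and 0 rose (4 and 0 adjusted over the list alone). Camera adjusted p was 0.0162 for both lists, and adjusted p = 0.124 and 0.425 with an estimated correlation. Mafa was at 0.06 (adjusted p = 0.913) and Pdx1 at -0.19 (0.359), and paired at -0.19 for Pdx1 (0.00382). Eif2a was at 0.37 (0.643), and paired at 0.34 (1.41e-06).

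The remaining lists gave no set call at 3 h in GFP cells. Rose and fell were 8 and 2 of 25 for cholesterol synthesis (camera adjusted p = 0.0750, paired 0.0193), 10 and 6 of 51 for translation factors (0.955), 5 and 5 of 35 for interferon response (0.406), and 5 and 5 of 19 for p53 targets (0.955). They were 2 and 1 of 23 for heat shock, 5 and 5 of 24 for autophagy and lysosome, and 3 and 6 of 23 for G2/M (0.955, 0.955 and 0.585). Among these lists median, mean and test differed in sign for translation factors, p53 targets, autophagy and lysosome, G2/M and delta/PP/epsilon, duct and mesenchymal markers. Genes disallowed in beta cells gave 0 of 8 calls by edgeR (camera adjusted p = 0.846). Markers of other cells gave 2 lower of 6 for alpha, 1 higher of 3 for acinar and 1 higher of 6 for duct cells, and no calls among 4 delta/PP/epsilon, 6 mesenchymal and 4 endothelial markers, all with camera adjusted p of 0.496 or more. Among 5 macrophage markers, C1qb and Csf1r rose by 5.34 ± 1.83 and 4.29 ± 1.59 (adjusted p = 0.0289 and 0.0421), where GFP replicate 4 at 3 h held 132 counts of Csf1r and the median of the list was -0.16, its mean 1.62. Paired, 4623 genes rose and 4611 fell at 3 h, all 4543 planned calls among them in the same direction. With scaling by library totals alone, 3361 rose and 1345 fell, as this scaling moved the median of all genes by 0.12. With an estimated correlation, 6 set calls hold at 3 h without replicate 1, namely ISR targets (adjusted p = 2.34e-05), immediate early genes and S phase (0.002825 each), tRNA synthetases (0.0119), granule genes (0.0253) and NRF2 targets (0.0447), and 0 hold paired (0.313 or more).

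**Figure D3:**
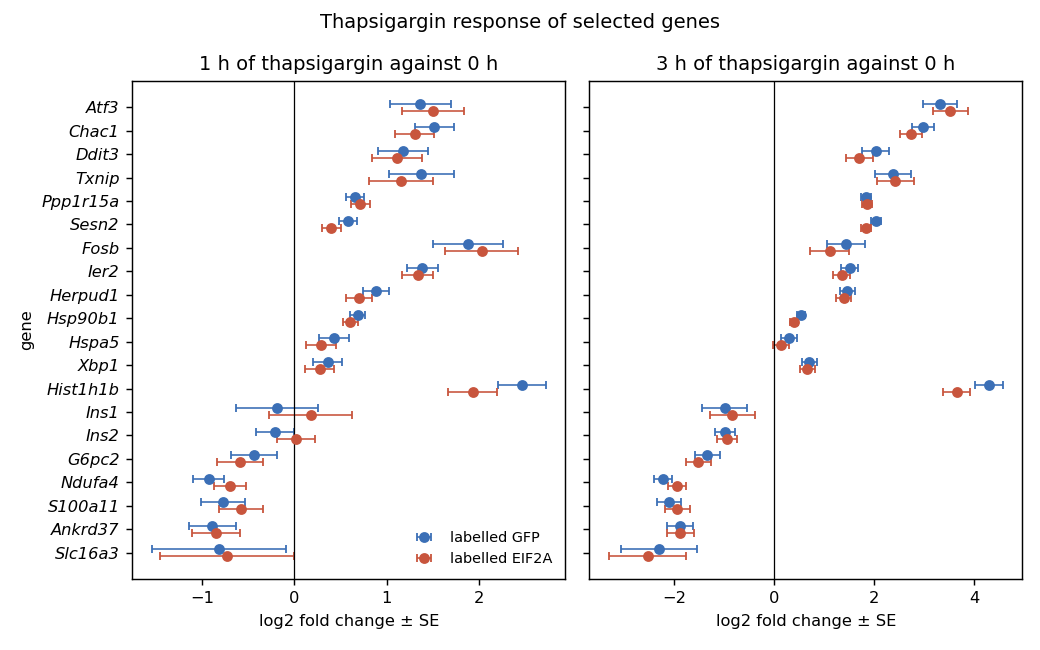
Log2 fold changes ± SE against 0 h of named genes after 1 and 3 h of thapsigargin in GFP and EIF2A cells, from the fit of all 24 libraries. In GFP cells Atf3 rises from 1.36 at 1 h to 3.32 at 3 h, and Ins2 goes from -0.21 to -0.98.

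From 1 h to 3 h in GFP cells, 756 genes rose and 589 fell, 118 and 18 by 2-fold or more (641 in all without GFP replicate 2 at 3 h). The cystine transporter Slc7a11 rose by 2.27 ± 0.25, the ATF4 target Trib3 by 1.99 ± 0.33 and Atf3 by 1.95 ± 0.33 (adjusted p = 9.43e-06, 5.87e-04 and 7.01e-04). Ddit3 rose by 0.85 ± 0.27 (0.0480), and Atf4 was at 0.22 (0.200). Of 38 ISR targets 29 rose and 0 fell (31 and 0 adjusted over the list alone; camera adjusted p = 5.18e-32; adjusted p = 0.00164 with an estimated correlation). Hist1h1e rose by 2.25. Lower at 3 h were C2cd4a (-1.43), S100a11 (-1.33), the tubulin gene Tuba1c (-1.31), Ndufa4 (-1.29) and Ins2 (-0.77 ± 0.20; adjusted p = 0.0201).

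Identity genes fell in 8 of 28 cases between 1 h and 3 h (10 adjusted over the list alone; camera adjusted p = 4.50e-06; adjusted p = 0.00690 with an estimated correlation). OXPHOS genes fell in 27 of 63 cases (41 adjusted over the list alone), with camera adjusted p = 4.57e-24 and adjusted p = 0.0302 with an estimated correlation. Of NF-κB targets 3 of 13 rose and 1 fell, of NRF2 targets 3 of 24 fell and of G2/M genes 7 of 23 fell. With an estimated correlation these 3 set calls have adjusted p = 0.0226, 0.0295 and 0.0295. Paired, all 6 calls named here are lost with an estimated correlation, at adjusted p = 0.166 (ISR), 0.0618 (identity), 0.170 (OXPHOS), 0.0618 (NF-κB), 0.232 (NRF2) and 0.208 (G2/M), and without replicate 1 all 6 hold (0.0339 or less). Ins1 was at -0.80 ± 0.45, Xbp1 at 0.35, Txnip at 1.00 and Pdx1 at -0.33 (adjusted p = 0.305, 0.175, 0.0728 and 0.175). Paired they were -0.82, 0.35, 1.07 and -0.33 (adjusted p = 3.82e-09, 6.03e-06, 1.78e-04 and 2.15e-05). Paired, 3464 genes rose and 3370 fell, and with library totals alone 1414 rose and 288 fell.

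Cells labelled EIF2A answered thapsigargin with many of the same genes. At 1 h, 902 genes rose and 542 fell, 55 and 5 by 2-fold or more (838 in all without replicate 3 and 2637 without replicate 1 at 1 h). Fosb rose by 2.03 ± 0.39, Atf3 by 1.501 ± 0.34, Chac1 by 1.30 ± 0.21 and Ddit3 by 1.11 ± 0.27 (adjusted p = 0.00207, 0.00599, 4.06e-04 and 0.0109). Txnip rose by 1.16, Herpud1 by 0.70 and Atf4 by 0.49. The histone genes Hist1h1b and Hist1h1d rose by 1.93 and 1.61, Rassf10 by 1.83, the snoRNA host gene Snhg12 by 1.57 and the actin binder Dbn1 by 1.45. Rragd, Tmsb4x and Ndufa4 were among the lowest, at -0.78, -0.72 and -0.70. Of 47 immediate early genes 13 rose (20 adjusted over the list alone), of 38 ISR targets 8 (8 adjusted over the list alone) and of 20 tRNA synthetases 10 (15 adjusted over the list alone), and 0 fell in each. Camera adjusted p was 2.62e-10, 0.00197 and 3.41e-09, and adjusted p = 0.146, 0.527 and 0.146 with an estimated correlation. Also higher as sets were ER chaperones (5 of 30), translation factors (6 of 51, with 1 lower), cholesterol synthesis (2 of 25), S phase (6 of 21) and G2/M (8 of 23), at camera adjusted p = 0.00197, 0.0149, 0.0112, 0.00664 and 0.00197. None of these 5 holds with an estimated correlation, at adjusted p = 0.626, 0.146, 0.679, 0.404 and 0.298. Without replicate 1, 6 set calls hold with an estimated correlation, namely immediate early genes (adjusted p = 5.06e-04), ER chaperones (0.00456), tRNA synthetases and cholesterol synthesis (0.0106 each), S phase (0.0313) and ISR targets (0.0354), and paired 0 hold (0.194 or more). Ins1, Ins2, Hspa5 and Xbp1 were at 0.18, 0.02, 0.29 and 0.28 with adjusted p of 0.3 or more, and paired Hspa5 and Xbp1 were at 0.30 and 0.29 (adjusted p = 5.71e-04 and 1.15e-04). Eif2a was at 0.42 (adjusted p = 0.727), and paired at 0.40 (5.41e-07). Paired, 3019 genes rose and 3213 fell.

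At 3 h in cells labelled EIF2A, 2702 genes rose and 2283 fell, 531 and 216 by 2-fold or more. Atf3 rose by 3.52 ± 0.35, Trib3 by 2.78 ± 0.34, Chac1 by 2.73 ± 0.22 and Ddit3 by 1.70 ± 0.28 (adjusted p = 1.74e-07, 1.80e-06, 1.21e-08 and 5.11e-05). Hist1h1b rose by 3.65, Hist1h1d by 3.62, Txnip by 2.43, Relb by 1.89, Herpud1 by 1.39, Xbp1 by 0.66 and Atf4 by 0.65. Among genes that fell, Slc16a3 was at -2.54, Ndufa4 and S100a11 at -1.94, Ankrd37 at -1.88, Tmsb4x at -1.73, Trappc1 at -1.71 and Tuba1c at -1.66. Ins2 fell by 0.94 ± 0.20 (adjusted p = 0.00103), from 58085 ± 5071 to 30266 ± 2817 CPM (SD, n = 4). Ins1 was at -0.84 (adjusted p = 0.156), and paired at -0.82 (3.57e-10). Bloc1s1 was at -0.49 ± 0.27 (0.170), Hspa5 at 0.13 (0.577), Mafa at -0.29 (0.541) and Pdx1 at 0.00 (0.988). Eif2a was at 0.43 (0.568), and paired at 0.42 (3.91e-08).

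The 11 set calls at 3 h were also made in GFP cells, where glycolysis and hypoxia was called too (camera adjusted p = 0.0636 here). ISR targets rose in 30 of 38 cases (30 adjusted over the list alone; camera adjusted p = 3.42e-17; adjusted p = 0.0369 with an estimated correlation), and tRNA synthetases in 17 of 20 (2.76e-09; 0.121). Camera called immediate early genes (14 rose of 47), S phase (15 of 21) and NF-κB targets (6 of 13, with 1 lower) upward at adjusted p = 0.00116, 7.60e-05 and 0.0455. It called OXPHOS (44 of 63 fell, 6 rose), ribosomal proteins (36 of 79, 1 rose), translocation and transport (16 of 35), identity (8 of 28, 2 rose), granule (6 of 24) and NRF2 targets (13 of 24, 2 rose) downward at adjusted p = 1.15e-09, 1.14e-08, 1.00e-04, 0.0455, 0.0175 and 0.00382. With an estimated correlation these 9 calls have adjusted p of 0.128 or more. Without replicate 1, 7 hold with an estimated correlation, namely ISR targets (adjusted p = 7.77e-05), S phase (0.00976), tRNA synthetases (0.0224), translocation and transport (0.0311), granule (0.03325), immediate early (0.0371) and NRF2 targets (0.0490), and paired 0 hold (0.431 or more). Paired, 4522 genes rose and 4583 fell, and with library totals alone 3813 rose and 1335 fell, as the median of all genes moved by 0.15.

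Between 1 h and 3 h in cells labelled EIF2A, 1140 genes rose and 911 fell, 151 and 22 by 2-fold or more (1248 in all without replicate 3 at 3 h). Hist1h1e rose by 2.52, Slc7a11 by 2.46 ± 0.26, Atf3 by 2.02 ± 0.33, Trib3 by 1.95 ± 0.32, the clock repressor Nr1d1 by 1.83 ± 0.12 and Txnip by 1.27 ± 0.35 (adjusted p = 3.28e-05, 4.42e-06, 3.48e-04, 4.48e-04, 1.76e-08 and 0.0161). Tuba1c, S100a11, C2cd4a and Tmem27 fell by 1.45, 1.36, 1.35 and 1.19, and Ins2 by 0.96. ISR targets rose in 29 of 38 cases, identity genes fell in 9 of 28 and OXPHOS genes in 41 of 63, and with an estimated correlation these 3 set calls have adjusted p = 0.00475, 0.0220 and 0.0384 (paired 0.192, 0.155 and 0.165). Ddit3, Ins1, Xbp1 and Mafa were at 0.59, -1.01, 0.39 and -0.41 (adjusted p = 0.151, 0.140, 0.0971 and 0.459), and paired at 0.68, -0.93, 0.38 and -0.51 (0.00538, 4.13e-10, 1.25e-06 and 0.0193). Paired, 3681 genes rose and 3566 fell, and with library totals alone 2604 rose and 349 fell, with the median of all genes moved by 0.17. Over all 12 contrasts 85 set calls were made, and 11 hold with an estimated correlation. These are ISR targets in the 4 contrasts of 3 h against 0 h or 1 h, identity and OXPHOS genes from 1 h to 3 h in both constructs, and NF-κB targets, NRF2 targets and G2/M from 1 h to 3 h in GFP. Without replicate 1, 55 of 107 set calls hold, all 11 among them. Paired, which leaves 8 contrasts, 2 of 77 hold, granule genes from 1 h to 3 h in GFP and EIF2A (lower; adjusted p = 0.0397 and 0.0427), and 0 of the 11. Paired, camera also called duct markers at 1 h in GFP (adjusted p = 0.0493) and EIF2A (0.0315), alpha markers from 1 h to 3 h in GFP (0.0416) and glycolysis at 3 h in EIF2A (0.0152), and it lost heat shock from 1 h to 3 h in EIF2A (0.0406 as planned, 0.0842 paired).

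The responses of both constructs, which share no libraries but come from the same fit with common gene dispersions, overlapped. Genes with little spread are called more easily in both, so the counts given for independence are a reference and not a test. At 1 h 592 genes rose in both (52.2 if independent), 74.4% of those that rose in GFP, and 273 fell in both (12.96 if independent). At 3 h 2233 rose in both (498.3 if independent) and 1757 fell in both (332.6). Across 13761 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.700 at 1 h and 0.872 at 3 h. Of 5538 genes called in either construct at 3 h, 32 had opposite signs.

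**Figure D4:**
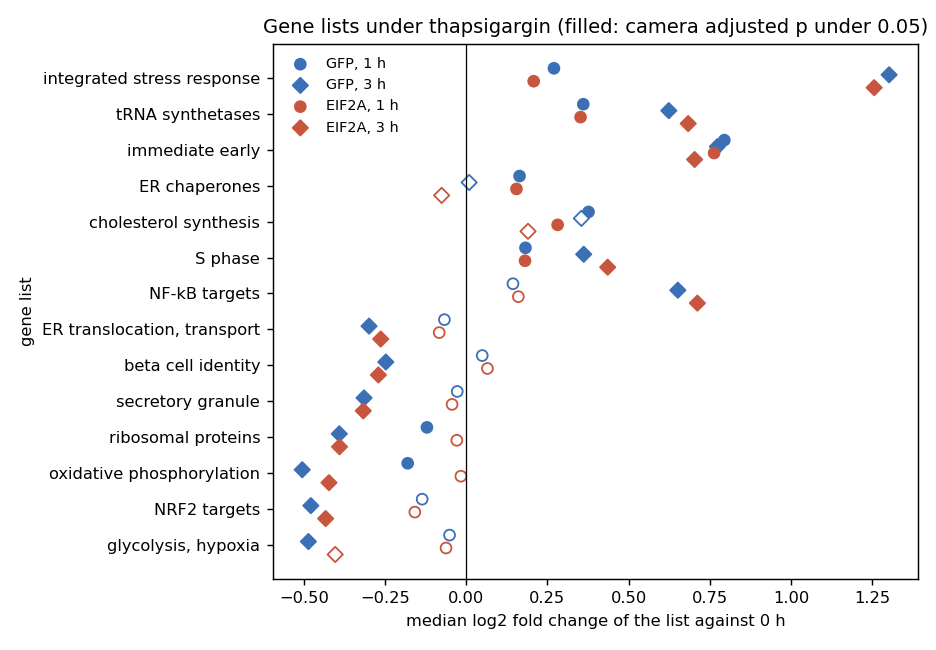
Median log2 fold change of gene lists against 0 h after 1 and 3 h of thapsigargin in GFP and EIF2A cells, with filled symbols where camera adjusted p was under 0.05. At 3 h the ISR list stands at 1.30 in GFP and 1.26 in EIF2A, and the OXPHOS list at -0.50 and -0.42.

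The comparison of constructs asks what differs between cells labelled EIF2A and GFP. Before thapsigargin, 1 gene was higher and 2 lower with all 4 replicates (0 in all without GFP replicate 2 and 2898 without EIF2A replicate 1 at 0 h). Tm6sf1, a lysosomal membrane gene, was at 0.56 ± 0.09, the histone demethylase gene Kdm3a at -0.66 ± 0.10, and Zfp109, chosen after its values were seen, at -1.44 (adjusted p = 0.0382, 0.0146 and 0.0382). Ins1 was at 0.96 ± 0.45 and Ddit3 at 0.70 ± 0.27 (0.221 and 0.163). At 1 h, 95 genes were higher and 46 lower. This count is 0 without GFP replicate 2 at 1 h or with the libraries of the contrast fitted alone, and 5391 without EIF2A replicate 1 at 1 h. Among these were Bloc1s1 at 1.14 ± 0.27, Dapl1 at 1.09 ± 0.24, the transcription factor gene Tcf4 at 0.76, Atp5k at 0.73, Park7 at 0.69, Rpl36a at 0.69, Cox5b at 0.58, Ppib at 0.56 and Ndufa5 at 0.46, with Kdm3a at -0.68 and Nr1d1 at -0.62. Scaled by library totals alone, 37 were higher and 158 lower at 1 h, the median of all genes having moved by -0.13. At 3 h edgeR called 0 genes, with 2901 at an unadjusted p under 0.05, and 3477 without EIF2A replicate 1 at 3 h. DESeq2 called 154 and limma-voom 0.

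Averaged over the 3 times, 3181 genes were higher in the libraries labelled EIF2A and 3035 lower. The nuclear RNA Malat1 was at 2.02 ± 0.32, Basp1 at 1.57 ± 0.48, Ins1 at 1.13 ± 0.26, Ddit3 at 0.57 ± 0.16 and Ins2 at 0.44 ± 0.12 (adjusted p = 3.90e-04, 0.0133, 0.00263, 0.00701 and 0.00632). The RNA-binding gene Rbfox1 was at -2.15 ± 0.84, the insulin receptor substrate gene Irs2 at -1.36 ± 0.36, Mafa at -0.52 ± 0.19 and Xbp1 at -0.22 ± 0.09 (0.0437, 0.00559, 0.0312 and 0.0493). With library totals alone 2348 were higher and 4151 lower. Of 79 ribosomal protein genes 74 were higher and 0 lower, with a median of 0.41 (camera adjusted p = 5.51e-22; adjusted p = 0.917 with an estimated correlation). Of 63 OXPHOS genes 46 were higher and 2 lower (2.91e-12; 0.622), and of 47 immediate early genes 2 higher and 11 lower (0.0282; 0.917). This average treats libraries of 1 construct at 3 times as separate, and with replicate number as a random effect 464 were higher and 299 lower.

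Without replicate 1, which was left out after seeing the data, the constructs differed in most genes. At 0 h 4385 were higher and 4519 lower in the libraries labelled EIF2A, at 1 h 4489 and 5120, and at 3 h 4458 and 4821. Some were near all or none. Aldh1a3, a marker of dedifferentiated beta cells, had 19 to 34 CPM in GFP and 0 to 0.35 in EIF2A in replicates 2 to 4 over the 3 times. The amino acid transporter Slc38a1 was at -5.75 ± 0.13, Emp1 at -6.49 ± 0.38, the hormone Ucn3 at -5.11 ± 0.22, Stc2 at -4.71 ± 0.25, Spp1 at -4.34 ± 0.08 and glucagon, Gcg, at -1.61 ± 0.04. Higher were the chloride channel Ano1 at 6.10 ± 0.20, Myo7b at 4.26 ± 0.13, Cdhr5 at 4.09 ± 0.15, Ces1d at 3.31 ± 0.12, the glucose transporter Slc2a2 at 1.82 ± 0.07, Ins1 at 1.48 ± 0.08 and Ddit3 at 1.12 ± 0.08. Mafa was at -0.61 ± 0.25 (adjusted p = 0.0399) and Pdx1 at 0.22 ± 0.10 (0.0594). With all 4 replicates these genes had adjusted p of 0.163 or more at 0 h.

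As sets without replicate 1, ribosomal protein genes were higher in 75 of 79 cases at 0 h and 76 at 1 h and at 3 h, with Rpl14 at 0.92 ± 0.05 at 0 h. The set medians were 0.54, 0.67 and 0.52 (camera adjusted p = 2.58e-15, 1.31e-18 and 3.31e-16). OXPHOS genes were higher in 45, 52 and 44 of 63 cases and lower in 6, 2 and 4 (5.97e-05, 1.03e-10 and 5.46e-07). With a trend on transcript length removed from each library, OXPHOS genes were higher in 22, 33 and 27 cases and lower in 16, 16 and 17, and the median went from 0.27, 0.46 and 0.32 to 0.03, 0.14 and 0.06. Ribosomal protein genes were then higher in 55, 57 and 50 cases and lower in 2, 2 and 3. Immediate early genes were lower in 27, 34 and 27 of 47 cases, and higher in 9 each time (0.0138, 0.00970 and 0.00253). Of 8 disallowed genes, 7, 6 and 7 were lower and 0 higher (0.00575, 0.0196 and 0.00239). With an estimated correlation none of these 12 calls holds, at adjusted p of 0.143 or more.

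Whether EIF2A changes the response to thapsigargin was tested as the interaction. With all 4 replicates edgeR called 0 genes at 1 h and 0 at 3 h, with 72 and 146 at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 at both times. Atf4, Ddit3, Atf3 and Ins2 had interactions of -0.16 ± 0.14, -0.33 ± 0.38, 0.21 ± 0.46 and 0.04 ± 0.29 at 3 h. Paired within constructs, 1 gene was called at 1 h and 2 at 3 h. These were Acta2 at -8.90 ± 1.24, with few counts, Flrt3 at -1.22 ± 0.17 and Pcdh10 at -0.58 ± 0.10 (adjusted p = 0.0141, 0.00351 and 0.0133), of which Acta2 and Pcdh10 were chosen after their values were seen. Camera called OXPHOS upward at both times (adjusted p = 6.43e-14 and 0.0402) and ribosomal proteins and translation factors upward at 1 h (9.55e-05 and 0.00556). It called mesenchymal markers downward at 1 h (6.08e-04) and autophagy and lysosome downward at 3 h (0.0402). None of these holds with an estimated correlation, at adjusted p of 0.161 or more. Paired, the mesenchymal call is lost (adjusted p = 0.0954) and glycolysis and hypoxia at 1 h is called upward (0.0612 as planned, 0.0132 paired), with adjusted p = 0.826 with an estimated correlation.

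Without replicate 1 the response differed between constructs in 112 genes at 1 h (67 with a higher and 45 with a lower value in the libraries labelled EIF2A) and 566 at 3 h (213 and 353). At 3 h the immediate early genes Sik1, Nr4a1, Nr4a2 and Fos had interactions of -2.19 ± 0.15, -1.72 ± 0.12, -1.59 ± 0.16 and -1.32 ± 0.15, and Npas4 of 1.28 ± 0.18. ISR genes had lower responses too, with Trib3 at -0.65 ± 0.10, Gpt2 at -0.63 ± 0.08, Chac1 at -0.63 ± 0.10, Ddit3 at -0.59 ± 0.10, Atf4 at -0.43 ± 0.07 and Mthfd2 at -0.39 ± 0.06. A lower response is not a lower level. The mean of Ddit3 was higher in EIF2A than in GFP at 0 h (121.9 against 56.2 CPM) and at 3 h (359.2 against 249.2 CPM). Hmgcs1 of cholesterol synthesis was at -0.85 ± 0.13, Flrt3 at -1.48 ± 0.14, Herpud1 at -0.35 and Hspa5 at -0.34, while Dyrk2 was at 1.31 ± 0.16 and Bloc1s1 at 1.14 ± 0.15. At 1 h Egr1 was at -1.06 ± 0.12, Fos at -0.93 ± 0.15 and Chac1 at -0.54, and Bloc1s1 at 1.06 ± 0.15, Atp5b at 0.55 ± 0.08 and Ndufa9 at 0.55 ± 0.08.

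Of 38 ISR targets 14 had a lower and 2 a higher response at 3 h without replicate 1 (16 and 2 adjusted over the list alone; median -0.22; camera adjusted p = 9.86e-06; adjusted p = 0.00826 with an estimated correlation). Cholesterol synthesis had 7 lower of 25 (9.86e-06; 0.00826) and immediate early genes 12 lower and 5 higher of 47 (0.00119; 0.0394). ERAD genes, with 4 lower of 24, autophagy and lysosome, with 1 lower and 1 higher of 24, and acinar markers, with 2 lower of 3, were also called (adjusted p = 0.0394, 0.0418 and 0.0394 with an estimated correlation). ER chaperones, translocation and transport, glycolysis and OXPHOS lose the call with an estimated correlation, at adjusted p = 0.0546, 0.0531, 0.463 and 0.791. At 1 h 11 of 63 OXPHOS genes had a higher response and 0 a lower (camera adjusted p = 1.42e-17; adjusted p = 0.144 with an estimated correlation), and ISR targets 1 and 3 of 38 (0.00275; 0.116). Camera also called ribosomal proteins, translation factors and glycolysis and hypoxia upward (1.77e-09, 0.003225 and 0.00206) and cholesterol synthesis downward (0.0180), with adjusted p of 0.144 or more with an estimated correlation. With the length trend removed, 6 OXPHOS genes had a higher response at 1 h and the median of the list went from 0.19 to 0.11. The ribosomal median went from 0.13 to 0.05, and 73 genes were called against 107 of those with a length.

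The response score set the mean of genes that rose against the mean of genes that fell, both chosen without regard to construct. These were 63 that rose and 1 that fell at 1 h, and 474 and 181 at 3 h. The 1 gene that fell at 1 h thus weighs as much as the 63 that rose together. At 1 h the score rose by 2.66 ± 0.61 in GFP and 1.94 ± 1.19 in EIF2A (SD of the responses of 4 equal numbers). At 3 h it rose by 2.56 ± 0.39 and 2.68 ± 0.41. The constructs differed by -0.72 at 1 h and 0.12 at 3 h on the log2 scale, with p = 0.248 and 0.502 in a two-sided exact permutation test over 4900 relabellings. At 1 h the value depends on the genes scored, at 0.03 (exact permutation p = 0.784) with a minimum log2 fold change of 0.5 (516 up and 114 down) and -0.22 (exact permutation p = 0.558) with a minimum of 2 (4 up and 0 down). Without replicate 1 the genes were chosen anew, 85 up and 8 down at 1 h and 575 and 242 at 3 h. The difference was then 0.08 at 1 h (exact permutation p = 0.430) and 0.16 at 3 h (exact permutation p = 0.01 over 400 relabellings). It was upward in the libraries labelled EIF2A, while the ISR and immediate early lists had lower responses. Relabelling at each time separately takes the constructs as exchangeable at 0 h, where they differed in 8904 genes. The permutation therefore does not test the response alone.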

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

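In this part the tests of exchanged labels, of the plasmid, of depth in replicate 1, of levels before thapsigargin and of the cell stock were chosen only after the results were seen, as was leaving out replicate 1. The test of depth for the 3 h difference was set before.

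Single libraries far from the 3 others of their group were sought for Eif2a, Ins1, Ins2, Ddit3, Hspa5 and the depth, 36 groups and measures in all. Chance gives about 1 in 20. There were 16, and all 16 were replicate 1. For Eif2a these were GFP at 0 h (269.4 CPM against 77.8 to 79.0), 1 h (361.2 against 90.2 to 94.3) and 3 h (358.1 against 91.2 to 101.9), and EIF2A at 0 h (80.3 against 134.0 to 142.3). For Ins1 they were GFP at 0 h (14510 CPM against 8082 to 8217), 1 h (13547 against 6779 to 7096) and 3 h (8279 against 3533 to 4001), and EIF2A at 0 h (7266 against 21291 to 23638). Ins2 stood apart in GFP at 0 h (60906 CPM against 40359 to 40656) and 3 h (34042 against 18397 to 20334). Ddit3 did in GFP at 0 h (85.4 CPM against 54.9 to 57.9) and EIF2A at 1 h (103.6 against 250.6 to 277.5). Hspa5 did in GFP at 0 h (1354 CPM against 1015 to 1057) and 3 h (1506 against 1302 to 1323), and in EIF2A at 1 h (1741 against 1324 to 1394) and 3 h (1934 against 1037 to 1144).

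Exchanged construct labels in replicate 1 are a candidate explanation. At 0 h the EIF2A minus GFP difference of replicate 1 runs against that of replicates 2 to 4 across genes (r = -0.738), and the same holds at 1 h and 3 h. This restates the arrangement that raised the question, so it cannot tell exchanged labels from other cells or plasmids. Right labels with a plasmid that adds reads to Eif2a are argued against, since the log2 ratio of EIF2A over GFP in replicate 1 averages -1.81 (SD 0.0794 over 3 times). Depth is argued against too, although EIF2A replicate 1 (16.9 to 22.07 M counts) lies above EIF2A replicates 2 to 4 (10.52 to 16.64), as r at 0 h stays at -0.727 (SD 0.00846 over 3 times) with all 24 libraries thinned to the lowest total. An exchange alone leaves a remainder. Eif2a in EIF2A replicates 2 to 4 lies below GFP replicate 1 by log2 values of -0.95, -0.93 and -0.93. GFP replicate 1 stands apart on the third principal component (41.3 to 46.9 against -18.8 to 11.5 in all others). EIF2A replicate 1 also lies above GFP replicates 2 to 4 on it, at 6.403 to 11.47 against -9.038 to 1.428. Its Hspa5 was 1490, 1741 and 1934 CPM at 0, 1 and 3 h, against at most 1057, 1515 and 1323 in them. Its Eif2a lies near theirs, at log2 values of 0.033, 0.073 and 0.098. Whether replicate 1 of both constructs shares a shift was not tested. Whether the labels, the cells or the plasmids differed stays open, and no library was regrouped.

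Without replicate 1 the response to thapsigargin differed between constructs, by a test of the interaction, in 112 genes at 1 h and 566 at 3 h. The response score at 3 h differed by 0.16 (exact permutation p = 0.01). Its relabellings take the constructs as exchangeable at 0 h too, so the permutation does not test the response alone. Splits drawn at each time in the same way gave as many as 566 genes in 11 of 100, the real one included. Depth is argued against as the whole cause of the 3 h difference, since 383 genes are called with all 18 libraries thinned to the lowest total, against 566 before. This count lies only just above the limit set in advance, so a part played by depth stays open. A higher level before thapsigargin is argued against for 12 immediate early genes with a lower response, whose difference at 0 h has a median of -0.91 (SE 0.41 over members). It stays open for 14 ISR genes (median 0.22, SE 0.20 over members), where the level and the response cannot be told apart. Both SEs take the members as independent. The cell stock, rather than the construct on the label, may be what the interaction follows: in replicate 1 it runs the other way at 3 h (r = -0.326 across genes, against 0.587 or more among replicates 2 to 4), with 448 of the 566 genes of opposite sign. An effect of EIF2A itself stays open, because exchanged labels in replicate 1 would give the same reversal.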

How the results depend on the processing

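In this part, leaving out all of replicate 1 and both uses of the replicate number within constructs were chosen only after the results were seen, and the other alternatives were planned. Changes in count follow from construction where genes below 2-fold were removed, and otherwise the cause was not tested. Counts of called genes are given in the order GFP at 1 h and 3 h against 0 h and 3 h against 1 h, then the same for EIF2A, where all 6 apply.

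No call of a named gene reversed direction under another scaling, tool or filter. Lists were compared under RLE scaling, with replicate number as a block across or within constructs, without replicate 1 and with 1 library left out. They were not compared under the other scalings, tools or filters. No list reversed under RLE scaling. Named genes kept direction and side of the threshold in 10311 tests, gained a call in 201 and lost one in 422, of which 346 came from leaving out 1 library, and lists in 10102, 133 and 56. Reversed were Eif2a (0.83), Atf3 (0.73) between constructs at 0 h and Fos in the interaction at 1 h (-0.93) with replicate 1 left out, and the ribosomal list in the interaction at 1 h without EIF2A replicate 1 at 0 h, with an adjusted p from 3.56e-13 (without EIF2A replicate 1 at 1 h) to 0.994.

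Leaving out replicate 1 gave 5413, 8648, 5798, 5762, 8598 and 6740 genes, 8904, 9609 and 9279 between constructs at 0, 1 and 3 h, 11178 over the times, and interactions of 112 and 566. Eif2a then was 0.83, 1.04 and 0.96 at the 3 times and 0.94 over them, and the score at 3 h 0.16. The replicate number within constructs as a block gave 6132, 9234, 6834, 6232, 9105 and 7247, and interactions of 1 and 2. As a random effect it gave 5561, 8818, 6271, 5642, 8689 and 6782, with 0 and 1085 between constructs at 0 h and 1 h and 763 over the times. As a block across both constructs it gave 2205 (GFP at 1 h), 2633 (GFP from 1 h to 3 h), 2791 (EIF2A at 1 h), 3335 (EIF2A from 1 h to 3 h), and 1333, 2890 and 1054 between constructs. This last block takes numbers as shared between constructs, where residuals of equal numbers correlate at -0.66 to -0.16. Without replicate 1 these correlations are -0.07 to 0.31, so the negative values depend on replicate 1.

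With the libraries of each contrast fitted alone, counts were 2417 and 2118 in GFP at 1 h and from 1 h to 3 h, 421 and 539 in EIF2A, and 0 and 0 between constructs at 0 h and 1 h. A 2-fold minimum left 51, 627, 136, 60, 747 and 173, 1 and 7 between constructs at 0 h and 1 h and 230 over the times. Between constructs at 0 h and 1 h, other choices gave 471 and 1637 (DESeq2), 1 and 33 (limma-voom), 1 and 1 (no filter), 5 and 535 (stricter filter) and 6 and 249 (upper-quartile). Library totals gave 5 at 0 h and 2 at 3 h, and DESeq2 154 at 3 h. Of 85 set calls 11 hold with an estimated correlation, of 107 without replicate 1 55, and of 77 paired 2.

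Leaving out 1 library at a time moved GFP at 1 h between 552 (without GFP replicate 2 at 1 h) and 1430, GFP at 3 h between 3775 and 5034, and GFP from 1 h to 3 h between 641 (without GFP replicate 2 at 3 h) and 1822. EIF2A moved between 838 (without replicate 3 at 1 h) and 2637 (replicate 1 at 1 h), 4214 and 5549, and 1248 (replicate 3 at 3 h) and 2829. Between constructs the ranges were 0 (GFP replicate 2 at 0 h) to 2898 (EIF2A replicate 1 at 0 h), 0 (GFP replicate 2 at 1 h) to 5391 (EIF2A replicate 1 at 1 h), 0 to 3477 (EIF2A replicate 1 at 3 h) and, over the times, 5119 to 8127. Interactions ran from 0 to 0 and from 0 to 3, and set calls from 81 to 100. Eif2a ran from -0.19 to 0.66, -0.14 to 0.85, -0.15 to 0.78 and -0.04 to 0.29, with each high value without GFP replicate 1 (at 0, 1, 3 and 1 h) and each low one without GFP replicate 3 or 4. The score ran from -1.002 to -0.46 at 1 h and -0.03 (without GFP replicate 1 at 3 h) to 0.30 at 3 h. With genes of at least 0.5 or 2 on the log2 scale it was 0.03 and -0.22 at 1 h, and 0.10 and 0.01 at 3 h.

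At these depths 4637 genes had no count. On simulated data the planned test found 36 to 44% of 2-fold interactions, and 90 to 91% without replicate 1. The simulated libraries were independent and lack the structure of replicate 1, so these shares need not hold for the real test.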

Other observations

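In this part the tests of genetically different cell stocks and of the plasmid, of transcript length for OXPHOS genes and of splits that keep equal numbers together, the set of histone genes and the fits without replicate 1 or paired by number were chosen only after the results were seen. The tests of depth, of transcript length for all genes and for ribosomal proteins, and of the other splits of the samples were set before.

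Many replication-dependent histone genes rose under thapsigargin, a set formed because single members stood out, so no test of the set is given. Of 54 measured, 10 rose at 1 h and 41 at 3 h in GFP cells (medians 0.40 and 1.84), and 8 and 48 in EIF2A cells (0.44 and 2.03), with 0 lower. Without replicate 1, 51 rose and 1 fell at 3 h in GFP and 52 and 0 in EIF2A. Their reads enter a polyA library only from tailed transcripts, and members share sequence, so more histone mRNA and more tailing of it were not separated here.

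The constructs of replicates 2 to 4 differ in far more genes than Eif2a, and among them the chromosome Y genes Ddx3y, Uty, Kdm5d and Eif2s3y have a median log2 fold change of -1.96 (SD 0.58; -2.66 to -1.44) at 0 h, against 0.37 for GFP at 3 h over 0 h. Cell stocks that differ genetically, such as by partial loss of the chromosome, are a candidate explanation, though lower transcription would look alike. Depth is argued against, as 8331 genes are called at 0 h with thinned libraries, and so is a trend with transcript length as the whole cause, as 8197 genes are called after its removal and 8577 before. After that removal the ribosomal list still has a median of 0.29 (SE 0.043 over members), against 0.54 before. The OXPHOS list has 0.033 (SE 0.055 over members), against 0.27 before, so the trend remains a candidate explanation for the OXPHOS difference at 0 h. These SEs take list members as independent and so understate the error, as ribosomal members have an estimated correlation of 0.58. The plasmid cannot be told apart from a difference in stock, if there was one: Eif2a is higher in the library labelled EIF2A in 9 of 9 pairs of replicates 2 to 4, and any such stock would carry 1 label there.

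Ddx3y stood at 34.7 to 48.2 CPM in GFP and 6.96 to 14.1 in EIF2A in replicates 2 to 4, and at 5.81 to 6.26 in GFP and 42.0 to 47.2 in EIF2A in replicate 1. Reads outside any gene made up 10.9 to 12.99% in GFP replicates 2 to 4, 13.3 to 17.9% in EIF2A replicates 2 to 4, 10.7 to 11.8% in GFP replicate 1 and 11.1 to 12.04% in EIF2A replicate 1. The construct differences without replicate 1 correlate with transcript length across genes at rho = -0.336, -0.382 and -0.350 at 0, 1 and 3 h. Macrophage transcripts were scattered: GFP replicate 4 at 3 h held 132 counts of Csf1r, 55 of C1qb and 40 of C1qc, EIF2A replicate 3 at 1 h held 45, 16 and 20, and EIF2A replicate 4 at 0 h held 23, 8 and 13.

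Other splits of the samples into groups of the same size tell how many genes chance calls. Libraries of equal number within a construct correlate at 0.51 to 0.93, but at -0.03 to 0.31 without replicate 1. It is thus not shown that numbers 2 to 4 mark pairs. If equal numbers are pairs, the fair splits within a construct are the 8 that part all 4 pairs, too few for a share under 0.05. Among these the highest other was 0 at 1 h, 1 at 3 h and 0 from 1 h to 3 h in EIF2A (1444, 4985 and 2051 genes), and 0 each time in GFP (1125, 4543 and 1345 genes). Among all 35 splits the highest other in GFP was 0 each time (1 of 35 as large, the real one), and in EIF2A 2060 at 1 h (3 of 35), 2550 at 3 h (1 of 35) and 3485 from 1 h to 3 h (2 of 35). The large others in EIF2A put both replicate 1 libraries on the same side, which points to the structure of the samples.

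Between constructs chance cannot be excluded at 0 h (3 genes, highest other 4313; 2 of 35) or 1 h (141, 5987; 3 of 35). At 3 h 0 genes were called, so every split gives as many by definition (35 of 35; highest other 4306) and the count tests nothing. The highest other in each is the split with replicate 1 exchanged, which again points to the structure of the samples. Over the 3 times, with libraries of equal number within a construct kept together, it cannot be excluded (6216, highest other 9792, with replicate 1 exchanged; 5 of 35). Splits drawn at each time separately (highest other 3854; 1 of 100) take these libraries as independent and decide nothing. Without replicate 1 the splits with equal numbers kept together are 10, too few for a share under 0.05 (11178 genes, highest other 0, and 7191 among splits drawn at each time; 1 of 100). Without replicate 1 the splits at a single time are 10, too few for a share under 0.05, with 8904, 9609 and 9279 genes at 0, 1 and 3 h and 0 as the highest other each time. For the interactions with all replicates 0 genes were called, so here too every split gives as many (100 of 100 each; highest others 4927 and 3686) and nothing is tested. Without replicate 1 chance cannot be excluded (112 and 566, highest others 10570 and 10431; 11 of 100). The highest other in each exchanges the constructs at 1 time, which points to the structure of the samples. This does not cover the remaining splits with as many calls, where the cause was not tested.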
